A study of Homo sapiens with 84 samples.

How the data were processed

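RNA was measured in human skin, in groups set by the labels: lesional and nonlesional skin of patients with psoriasis and skin of healthy donors, each sampled as an intact punch biopsy, as a biopsy from beneath a tape-stripped area and as the tape itself. Per the labels' protocols, RNA was extracted with the RNeasy kit and made into libraries with Takara's SMARTer kit for pico amounts, a stranded kit which reverse-transcribes total RNA from random primers, and parallel samples were made with the Lexogen QuantSeq FWD kit, which primes at poly(A) tails. A label on 10 lesional tape libraries was taken to mark the Lexogen kit, and the other 74 libraries were taken to be Takara. The values used were counts per gene symbol, which the authors deposited as 1 table of whole numbers without normalization. Per the submitters' processing notes, STAR, HTSeq and the hg19 build were used. Their versions, the annotation release, the strand setting, the treatment of duplicate reads and any filter are not given in the sources used here. Each feature had at least 84 counts summed over the 84 libraries of the table, from which the work started.

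A count of this kind depends on steps before it. Genes with near-identical copies share reads, so values of DEFB4A, S100A7 and S100A7A, the SPRR2, LCE3, KRT6 and KRTAP families, 5S and other ribosomal RNA copies and pseudogenes are uncertain. Without a known strand setting, overlapping and antisense genes cannot be separated. Reads without molecular identifiers are not independent molecules, so intervals and floors given here cover counting error only. XIST and Y-linked features (46 of 31248) were left out, which left 31202. Because they included a ribosomal RNA pseudogene, tape totals fell. Mean totals were 468052 counts in healthy, 3019833 in nonlesional and 6810245 in lesional Takara tape as deposited and 443161, 2485923 and 5410823 over the features kept, against 19602795 and 19592087 in biopsies. Total counts are given for the table as deposited, and shares, CPM and tests use the features kept. Gene type and exon length came from GENCODE v29 by symbol, which matched 22363 features (71.7%), and no coordinates were used. Ribosomal RNA was summed over 134 features, 130 of them by name. Between libraries of 1 group the smallest chi-square per degree of freedom was 12.46, so none were merged as duplicates.

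The main test was the quasi-likelihood test of edgeR 4.0.16 with TMM scaling, filterByExpr at its defaults and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Contrasts between skin states within 1 material were fitted on the libraries of all 3 states, and contrasts between materials or kits on the groups compared. The difference in lesional effect between materials was an interaction term over 4 groups. Fold changes are on the log2 scale, with SE taken from the fold change and its F statistic, and CPM are scaled by TMM factors. A positive value means higher in the group named first. Where a group had no counts, the fold was computed against a floor of 3 counts over the group and given as a bound. Where it had 1 to 3 counts, the ratio is given with an exact 95% counting interval. Genes detected were compared by two-sided permutation tests, exact where a group held under 10 libraries and otherwise with 100000 resamples. Correlations across genes describe these fold changes and carry no test. Correlations across patients were given permutation p-values and adjusted over 42 genes.

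Gene sets were 34 lists of marker and pathway genes. They covered the IL-17 response of keratinocytes, the IL-23/IL-17 axis, both interferon responses, cornification, barrier and sebaceous lipids, keratinocyte layers, proliferation, wound repair, cells of the dermis, skin appendages and immune system, blood, and RNA classes. KRT16, KRT17 and KRT6A stood in both the IL-17 and the wound list, and MMP9 in the neutrophil and wound lists. Some members of the lists are not reported here. Members were counted when adjusted over all genes tested and, separately, when adjusted over the list alone. Each list was tested against all other genes with camera of limma 3.58.1 at its preset correlation, and again with a correlation estimated from the data and with fry. Camera p-values were adjusted over the lists of a comparison. In all, 564 list tests were made. Genes named in the text followed a rule. It took the 5 largest rises and falls among called genes with at least 10 CPM in the higher group, leaving out symbols that are clone names, then a short list of marker genes, then from each list up to 4 members with the smallest adjusted p and members that went against their list. Immunoglobulin, T cell receptor and HLA genes were not named. The absent symbols PECAM1, SOX10, UBD and IL21 were not analysed here. The lists, the rule, the group comparisons and the settings to be varied, apart from the additions given below, were chosen before the data were examined.

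Libraries with the same number came from the same donor per the labels, so the donor was used as a block in a further fit. Within a group each library's deviation from the group mean was correlated with that of the same donor elsewhere. Median same-donor correlations were 0.31 between lesional and nonlesional biopsies (-0.03 between other donors), 0.21 for biopsies under tape and 0.06 for tape. Between biopsies under tape and intact biopsies they were 0.41 in lesional, 0.48 in nonlesional and 0.51 in healthy skin, between tape and biopsies 0.05, 0.08 and 0.03, and between kits 0.15. Other settings tried were DESeq2 size factors, upper-quartile factors, the Wald test of DESeq2 1.42.0, limma voom with sample weights, no low-count filter, a fold of at least 2 beside the adjusted p, shallow libraries left out, libraries with at least 1000000 counts thinned to 1 depth, only the groups compared, and each healthy replicate left out in turn. In the fits that depth was the smallest such library of the groups fitted. For genes detected it was 1182988 counts in all groups. Added after seeing the data were ribosomal RNA features left out, thinning to 200000 counts, and leaving out 3 patient Takara tape libraries, with the Lexogen libraries of the same samples, in which nuclear protein-coding genes held over 60% of counts.

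The tests were tried on simulated counts drawn with the means, spreads and totals of the real libraries, with 67 genes changed by 2-fold, 67 by 4-fold and 66 by 8-fold. For lesional against nonlesional biopsies (19081 genes) 74.6%, 94.0% and 97.0% of the changed genes were called, and 4.3% of calls were of unchanged genes. For the same contrast in tape (20873 genes) 0%, 4.5% and 22.7% were called, and 10 of 28 calls were of unchanged genes. With healthy tape the 8-fold changes called were 1.5% against lesional and 3% against nonlesional tape. For tape against lesional biopsies (16011 genes) they were 77.3%, for Lexogen against Takara (7363 genes) 22.7%, and for the interaction of lesion and tape (19333 genes) 12.1%. Correlation between genes was not simulated, so its effect on list calls was not tested. Camera found a list of 4-fold rises in each of the 9 comparisons simulated and called 0 of 20 unchanged lists. Between tape groups, most changes of 2-fold to 8-fold were thus not called. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.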

Results

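Psoriatic and healthy human skin was sampled by tape stripping and punch biopsy for RNA sequencing. Tape stripping lifts the outermost layers of the epidermis on adhesive tape, whereas a punch biopsy takes epidermis and dermis together. Biopsies of 6 mm were taken from skin left intact and from skin beneath a stripped area. The protocol did not plainly state from which skin each biopsy beneath tape came, so those groups followed the sample titles. Lesional skin of patients gave 10 intact biopsies, 10 biopsies under tape and 10 tape samples. Nonlesional skin of patients gave 9 intact biopsies, 10 biopsies under tape and 10 tape samples, and healthy donors gave 5 of each. RNA of the 10 lesional tape samples was also made into libraries with a Lexogen 3' kit, which reads the 3' ends of polyadenylated transcripts. The other libraries were taken to be Takara total RNA, though the biopsy labels name no kit. The 84 libraries held gene counts for 31248 features.

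Sequencing depth differed between the materials, with ranges that overlapped except in healthy tape. The 49 biopsy libraries held a median of 20215238 counts (9945190 to 25687588). Takara tape libraries held a median of 5819165 counts in lesional skin (3873172 to 13314333), 1382746 in nonlesional skin (508715 to 11692646) and 322265 in healthy skin (234994 to 911394). All 5 healthy and 4 of the 10 nonlesional tape libraries held under 1000000 counts. The 10 Lexogen libraries held a median of 4488218 (1386892 to 31334048). Features that collect ribosomal RNA took a median of 75.8% of counts in lesional, 49.2% in nonlesional and 27.9% in healthy Takara tape. They took 1.35% in Lexogen tape and group medians of 0.295% to 0.423% in biopsies. In Lexogen tape mitochondrial transcripts took a median of 59.2%. Nuclear protein-coding genes held 14.6%, 36.5% and 55.3% of counts in lesional, nonlesional and healthy Takara tape. In 3 patient Takara tape libraries, 2 of them lesional, that share was at least 80.7%, and the next highest was 46.1%.

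**Figure D1:**
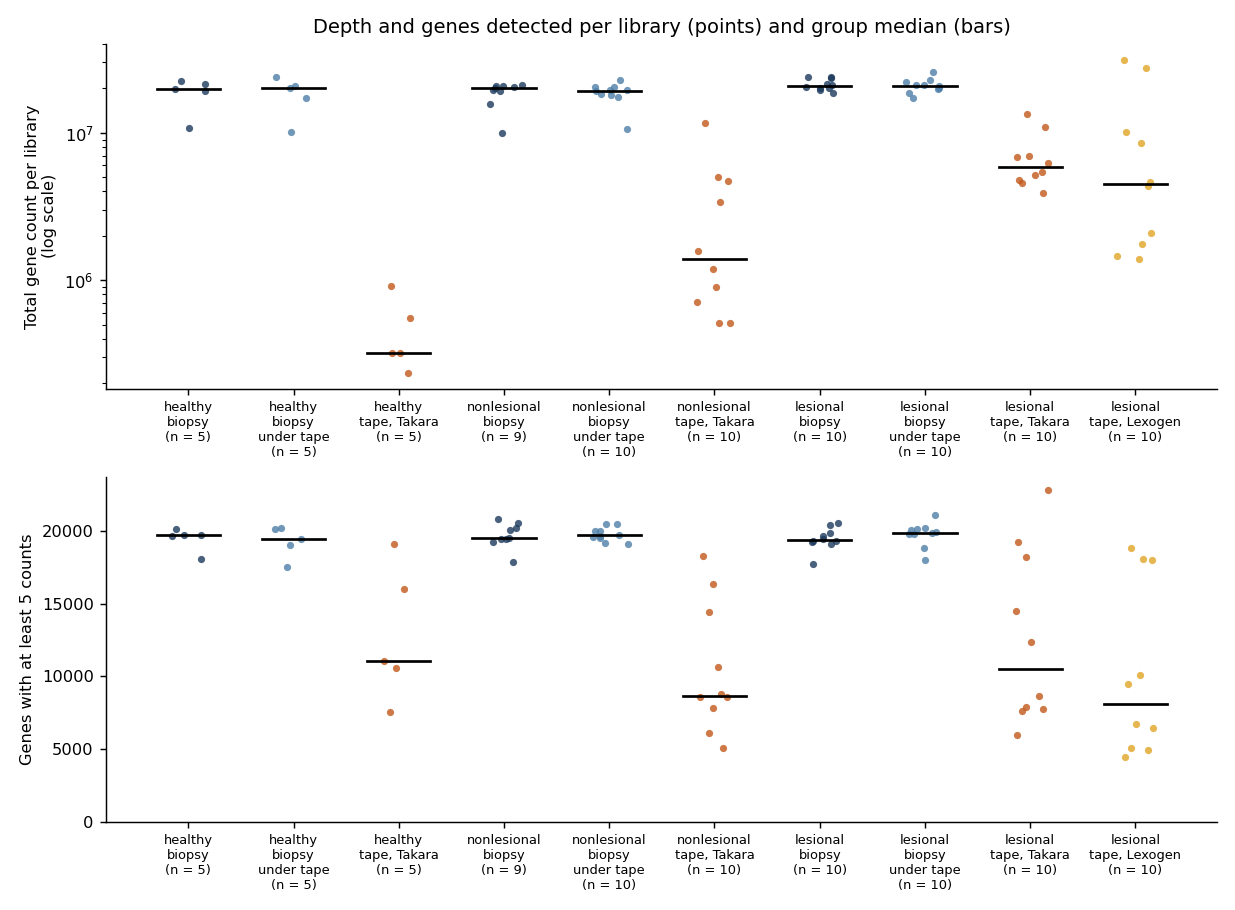
Total deposited counts per library (log axis) and genes with at least 5 counts per library, by group, with each library as a point. The 5 healthy tape libraries lay between 234994 and 911394 counts, below every biopsy library.

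Fewer genes were detected in tape than in biopsies at the deposited depth. Lesional tape gave 12477 ± 5901 genes with at least 5 counts (mean ± SD, n = 10) and lesional biopsies 19465 ± 790 (n = 10; two-sided permutation p = 0.00254, adjusted p = 0.0127 over 10 comparisons). Nonlesional tape gave 10454 ± 4434 (n = 10) and nonlesional biopsies 19682 ± 873 (n = 9; exact permutation p = 4.33e-05, adjusted p = 0.000433). Healthy tape gave 12859 ± 4620 and healthy biopsies 19458 ± 817 (n = 5 each; exact permutation p = 0.0159, adjusted p = 0.0529). At 1 depth of 1182988 counts lesional tape gave 8249 genes and lesional biopsies 12549, a similar ratio (0.657 against 0.641), at permutation p = 0.0146, adjusted p = 0.0599. In nonlesional tape only 5 libraries reached this depth. With at least 10 counts the lesional difference passed at that depth (permutation p = 0.00252, adjusted p = 0.0101), though not within donors (sign-flip permutation p = 0.0156, adjusted p = 0.125). It passed as well at 200000 counts, a depth chosen after the data were seen, with 2689 and 7406 genes (permutation p = 8e-05, adjusted p = 0.0004) and in nonlesional skin 3400 and 7452 (exact permutation p = 2.17e-05, adjusted p = 0.000217). In healthy skin the direction at 200000 counts turned with the minimum. Tape gave 18705 genes and biopsies 13357 with at least 1 count (exact permutation p = 0.00794, adjusted p = 0.0397), 8224 and 7354 with at least 5 (exact permutation p = 0.0714, adjusted p = 0.179) and 3759 and 4343 with at least 10 (exact permutation p = 0.0159, adjusted p = 0.0397). Lexogen libraries gave 10204 genes and Takara libraries of the same samples 12477 (permutation p = 0.392, adjusted p = 0.645; within-donor sign-flip permutation p = 0.00781, adjusted p = 0.0352). At 1 depth this held with at least 1 count (10456 and 13679 genes, adjusted sign-flip permutation p = 0.0312). It did not with at least 5 (7470 and 8249, adjusted p = 0.453) or 10 (adjusted p = 0.875). At 5 it turned at 200000 counts (3015 and 2689, adjusted p = 0.541). Biopsies under tape and intact biopsies differed by less than the spread between libraries, at adjusted permutation p-values from 0.645 to 0.798.

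Lesional biopsies (n = 10) were compared with nonlesional biopsies (n = 9). The antimicrobial and cytokine genes that keratinocytes make in response to IL-17 rose nearly as a set: 28 of 29 members rose (28 adjusted over the list alone), at camera adjusted p = 6.03e-24 and adjusted p = 0.131 with an estimated correlation. S100A9 and S100A8, which together form calprotectin, rose from 119 ± 155 to 9036 ± 4824 and from 101 ± 149.6 to 5748 ± 3010 CPM (counts scaled to the library total, mean ± SD), with edgeR adjusted p-values of 1.97e-06 and 3.59e-06. The largest rises among genes with at least 10 CPM were those of IL36A, an epithelial cytokine of the IL-1 family (log2 fold change 9.13, SE 0.96, adjusted p = 7.08e-07), S100A7A (8.05, SE 0.82), IL19 of the IL-20 cytokine family (8.02, SE 1.28), the protease inhibitor SERPINB4 (7.91, SE 0.96) and SPRR2C (7.61, SE 0.78). Beta-defensin gene DEFB4A (7.45), the elastase inhibitor PI3 (6.90), psoriasin gene S100A7 (4.70), KRT16 (5.13) and KRT6A (4.03), keratins of wounded and fast-growing epidermis, and the chemokines CXCL1 (5.06), CXCL8 (5.31) and CCL20 (2.97) rose as well, with adjusted p-values up to 0.00183. In the list for the IL-23/IL-17 axis, 6 of 13 members rose and 2 fell (8 and 2 adjusted over the list alone). IL17A, with 1 count over all nonlesional biopsies, was 105-fold higher (95% exact counting interval 18.5 to 4184). IL12B (3.79) and IL23A (1.57) rose. The receptor subunit IL17RC (-0.74) fell. As a whole the list had camera adjusted p = 0.214.

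Interferon-response genes and some immune-cell genes rose alongside. Of the type I interferon response genes, 26 of 26 members rose (26 adjusted over the list alone), at camera adjusted p = 3.09e-25 and adjusted p = 0.131 with an estimated correlation. The RNA sensor gene OASL rose by 3.89 (SE 0.46, adjusted p = 3.41e-06). In the interferon-gamma response, 15 of 19 members rose (17 adjusted over the list alone), at camera adjusted p = 5.25e-11 and adjusted p = 0.14 with an estimated correlation. The chemokine CXCL10 rose by 2.36. For T cells 8 of 21 members rose (8 adjusted over the list alone), at camera adjusted p = 1.98e-06 and adjusted p = 0.367 with an estimated correlation. CTLA4 and FOXP3, both markers of regulatory T cells, rose by 2.17 and 1.46. For cytotoxic cells 6 of 12 members rose (7 adjusted over the list alone), at camera adjusted p = 0.000109 and adjusted p = 0.29 with an estimated correlation. The granule protease GZMB rose by 3.67. For macrophages 4 of 15 members rose (4 adjusted over the list alone), at camera adjusted p = 0.0184 and adjusted p = 0.65 with an estimated correlation. For dendritic cells 5 of 16 members rose (7 up and 2 down adjusted over the list alone), at camera adjusted p = 0.00776 and adjusted p = 0.57 with an estimated correlation. LAMP3, a marker of their mature form, rose by 1.85. For neutrophils 5 of 13 members rose (9 adjusted over the list alone), at camera adjusted p = 0.000274 and adjusted p = 0.29 with an estimated correlation. Their chemokine receptor CXCR2 rose by 1.98. Langerhans cell markers went the other way: 4 of 8 members fell (4 adjusted over the list alone), at camera adjusted p = 0.0101 and adjusted p = 0.29 with an estimated correlation. CD207, the langerin gene, fell by 1.30 and the antigen-presenting CD1A fell by 1.21. Proliferation genes rose throughout: 24 of 24 members rose (24 adjusted over the list alone), at camera adjusted p = 9.99e-17 and adjusted p = 0.251 with an estimated correlation. The ribonucleotide reductase subunit RRM2 rose by 2.37 and the mitotic motor KIF11 rose by 1.30. The list of wound-repair genes of keratinocytes shares KRT16, KRT17 and KRT6A with the IL-17 list. Of its genes 11 of 18 members rose (15 up and 1 down adjusted over the list alone), at camera adjusted p = 1.05e-05 and adjusted p = 0.284 with an estimated correlation. The growth factor EPGN rose by 4.87.

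Genes of the epidermal barrier were examined as early and late lists. Small proline-rich and LCE3 genes of the early cornified envelope rose: 15 of 17 members rose (17 adjusted over the list alone), at camera adjusted p = 1.19e-16 and adjusted p = 0.131 with an estimated correlation. Of the late cornification genes 2 of 25 members rose and 4 fell (2 and 4 adjusted over the list alone), at camera adjusted p = 0.0177 and adjusted p = 0.651 with an estimated correlation. HRNR (4.72) and TGM3 (1.61) rose, and KRT77 (-2.16) and LCE5A (-2.12) fell. The filaggrin gene FLG stood at -1.18, adjusted p = 0.15, and at -2.02 with adjusted p = 0.0319 with the replicate block. The loricrin gene LOR stood at -1.33, adjusted p = 0.0643, and at -2.09 with adjusted p = 0.0289 with the block. Of the genes of epidermal barrier lipids 8 of 18 members rose and 1 fell (9 and 3 adjusted over the list alone), at camera adjusted p = 0.0184 and adjusted p = 0.65 with an estimated correlation. Sebaceous lipid genes showed the largest falls: 3 of 22 members rose and 16 fell (3 and 19 adjusted over the list alone), at camera adjusted p = 0.000179 and adjusted p = 0.578 with an estimated correlation. The steroid dehydrogenase HSD3B1 fell by 5.89 (SE 1.16, adjusted p = 0.000763) and the lipogenesis regulator THRSP fell by 3.48. SQLE (0.91) of cholesterol synthesis rose within the same list. GAL (-4.40), AADACL3 (-4.29), PDE6A (-4.18) and HAO2 (-3.92) completed the 5 largest falls. The Wnt inhibitor WIF1 (-3.49) and the growth factor BTC (-2.70) fell too. Mitochondrially coded transcripts fell (11 of 13 down, 11 adjusted over the list alone, camera adjusted p = 4.71e-06), with adjusted p = 0.367 with an estimated correlation. The ribosomal protein list shifted down with 2 of 26 members passing (camera adjusted p = 0.00184), with adjusted p = 0.65 with an estimated correlation. So did the lists for smooth muscle and pericytes (0 of 14, camera adjusted p = 0.0394), Schwann cells (2 of 9, camera adjusted p = 0.00303) and blood (1 of 6, camera adjusted p = 0.0297), with adjusted p = 0.65, 0.398 and 0.514 with an estimated correlation.

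The other 13 lists had no set-level shift in biopsies. These were basal (2 up and 2 down of 16; camera adjusted p = 0.571) and suprabasal keratinocytes (1 up of 16; 0.311), fibroblasts and matrix (1 up and 1 down of 20; 0.321), endothelium (2 down of 16; 0.0646), adipocytes (2 down of 13; 0.13), melanocytes (1 down of 10; 0.502), mast cells (2 down of 10; 0.0981), B and plasma cells (1 up of 7; 0.791), sweat glands (0 of 14; 0.644), hair follicles (0 of 15; 0.758), replication histones (0 of 4; 0.791), small structural RNAs (0 of 6; 0.928) and immediate early genes (1 up and 1 down of 18; 0.962). Across all genes, edgeR called 2609 rises and 1860 falls among 19081 tested. At least 2-fold changes made up 792 and 702 of these. Upper-quartile scaling, which moved the median of all genes by -0.093 on the log2 scale, turned the balance to 2103 rises and 2276 falls.

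The same contrast was made in biopsies beneath the stripped area (n = 10 each). The IL-17 response rose again: 26 of 29 members rose (26 adjusted over the list alone), at camera adjusted p = 2.91e-27 and adjusted p = 0.0397 with an estimated correlation. IL36A (log2 fold change 8.76, SE 1.01, adjusted p = 7.28e-06), S100A7A (6.80), SERPINB4 (6.45) and the calcium-binding alarmin S100A12 (6.34) had 4 of the 5 largest rises. Type I interferon genes rose without exception in this list (26 of 26 up, 26 adjusted over the list alone, camera adjusted p = 5.72e-32), with adjusted p = 0.0397 with an estimated correlation. OAS2 rose by 3.33 and IFI6 rose by 3.03. Interferon-gamma genes followed (18 of 19 up, 19 adjusted over the list alone, camera adjusted p = 4.6e-19), with adjusted p = 0.0397 with an estimated correlation. The guanylate-binding protein genes GBP1 and GBP5 rose by 1.70 and 1.95. Of T cell genes 17 of 21 members rose (20 adjusted over the list alone), at camera adjusted p = 1.01e-17 and adjusted p = 0.0567 with an estimated correlation. Of cytotoxic genes 11 of 12 members rose (11 adjusted over the list alone), at camera adjusted p = 1.84e-11 and adjusted p = 0.0397 with an estimated correlation, and GZMB rose by 3.85. Of macrophage genes 11 of 16 members rose (13 adjusted over the list alone), at camera adjusted p = 1.76e-09 and adjusted p = 0.155 with an estimated correlation. Of neutrophil genes 8 of 11 members rose (10 adjusted over the list alone), at camera adjusted p = 2.58e-07 and adjusted p = 0.0397 with an estimated correlation. Proliferation genes rose (24 of 24 up, 24 adjusted over the list alone, camera adjusted p = 1.66e-13), as did small proline-rich and LCE3 genes (15 of 17 up, 16 adjusted over the list alone, camera adjusted p = 3.16e-16), with adjusted p = 0.207 and 0.0409 with an estimated correlation. SPRR2A rose by 6.28 and LCE3A rose by 5.83. Of late cornification genes 2 of 25 members rose and 8 fell (2 and 12 adjusted over the list alone), at camera adjusted p = 1.4e-07 and adjusted p = 0.305 with an estimated correlation. LOR fell by 1.78 (adjusted p = 0.0414). WIF1 (-3.58), the adipokine SERPINA12 (-3.04), the anti-inflammatory cytokine IL37 (-3.04), SYT8 (-2.89) and BTC (-2.77) had the largest falls. The edgeR test called 1808 rises and 1122 falls among 19074 genes, and 696 and 384 of at least 2-fold. With the replicate block the calls were 1565 rises and 1464 falls.

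In tape, few genes were called between lesional (n = 10) and nonlesional (n = 10) samples, in a contrast where 22.7% of simulated 8-fold changes were called. Genes of hair shaft keratins and their associated proteins made up the largest falls. KRTAP4-7 (log2 fold change -10.40, SE 1.45, adjusted p = 3.03e-06), KRTAP3-2 (-10.22) and KRTAP4-8 (-10.17) were among the 5 largest, and KRTAP3-1 was 8761-fold lower (95% exact counting interval 2997 to 42489), with adjusted p-values up to 1.06e-05. In the hair follicle list 5 of 15 members fell (5 adjusted over the list alone), at camera adjusted p = 1.87e-07 and adjusted p = 0.0501 with an estimated correlation. Of the summed CPM of 92 hair keratin and keratin-associated genes in nonlesional tape, 95.7% lay in 2 of the 10 libraries. Group medians, with ribosomal RNA in the total, were 52.9 CPM in lesional, 694 in nonlesional and 577 in healthy tape. IL26, a cytokine of IL-17-producing T cells, had no counts in lesional and 53 in nonlesional tape, so at least 33.4-fold lower (edgeR adjusted p = 0.0075). Healthy tape held 16 counts (pooled CPM 2.577 against 1.641 in nonlesional tape). The IL-17 response genes shifted upward as a list without a single member passing. Of them 0 of 29 members passed (0 adjusted over the list alone) and the median log2 fold change was 1.12, at camera adjusted p = 1.16e-28 and adjusted p = 0.0501 with an estimated correlation. S100A9 stood at log2 fold change 1.49, SE 0.73, adjusted p = 0.871, KRT16 at 1.11, adjusted p = 1 and PI3 at 1.60, adjusted p = 0.763. The same held for type I interferon genes (median 0.77, camera adjusted p = 5.72e-22), small proline-rich and LCE3 genes (3.04e-16), barrier lipid genes (1.2e-07) and wound-repair genes (9.63e-08). None of their 26, 18, 18 and 18 members passed, also when adjusted over the list alone. With an estimated correlation camera adjusted p was 0.00602, 0.108, 0.0533 and 0.0316. The interferon-gamma list (camera adjusted p = 6.83e-05 and 0.116 with the replicate block) and the proliferation list (camera adjusted p = 0.000723 and 0.152 with the replicate block) were not called with the block, with adjusted p = 0.099 and 0.516 with an estimated correlation. Of 20873 genes tested with edgeR, 2 rose and 179 fell. The 2 risers were CEACAMP1, a pseudogene at least 36.3-fold higher, and the lncRNA clone RP4-659I19.1, at least 25.6-fold higher. The second is named after its values were seen. With the replicate block 17 genes were called and without the shallow libraries 3, and in simulated libraries of this depth 10 of the 28 calls were of unchanged genes.

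Lesional effects in tape and biopsy were compared directly. Across 16167 genes, the lesional fold changes in tape and in intact biopsy had a Pearson correlation of 0.098 (Spearman 0.125) and shared direction for 54.3%, and for 59.6% of the 4050 genes called in biopsies. Genes are not independent replicates, so these values are descriptive. Between biopsies under tape and intact biopsies the correlation was 0.831 (Spearman 0.757) across 18711 genes, and 97.4% of 4417 called genes shared direction. Of the genes called in both kinds of biopsy, 1323 rose and 671 fell in both, where lists drawn independently would share 249 and 108. In tape and intact biopsy 6 genes fell in both, where independent lists would share 10.4. The interaction of lesion and material was then fitted. IL-17 response genes had smaller lesional effects in tape than in biopsy: 17 of the 30 members passed downward (25 adjusted over the list alone), at camera adjusted p = 1.72e-17 and adjusted p = 0.467 with an estimated correlation. The difference in log2 fold change was -8.20 for IL36A (SE 1.37, adjusted p = 0.00125), -6.52 for SERPINB4, -6.66 for S100A7A, -4.46 for S100A8, -5.30 for PI3 and -4.00 for KRT16, with adjusted p-values up to 0.00867. SPRR2A (-5.71), HRNR (-5.41) and GZMB (-7.09) passed in the same direction. HSD3B1 (6.26), KAZALD1 (4.34) and CEACAM6 (3.31) had higher effects in tape, of which KAZALD1 and CEACAM6 did not pass with the replicate block (adjusted p = 0.334 and 0.0977). Sebaceous genes as a list went the same way as HSD3B1, with 1 of 22 members passing (12 adjusted over the list alone, camera adjusted p = 2.14e-15), with adjusted p = 0.455 with an estimated correlation. In all, 23 genes had a higher and 136 a lower lesional effect in tape among 19333 tested, 4 and 33 with the replicate block, and 0 with voom weights set per material (756 at unadjusted p under 0.05). For biopsies under tape against intact biopsies, edgeR called 0 genes (674 at unadjusted p under 0.05; 0 by DESeq2 and by voom), while the T cell list had a larger lesional effect under tape (median 0.56, camera adjusted p = 8.18e-08), with adjusted p = 0.704 with an estimated correlation.

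**Figure D2:**
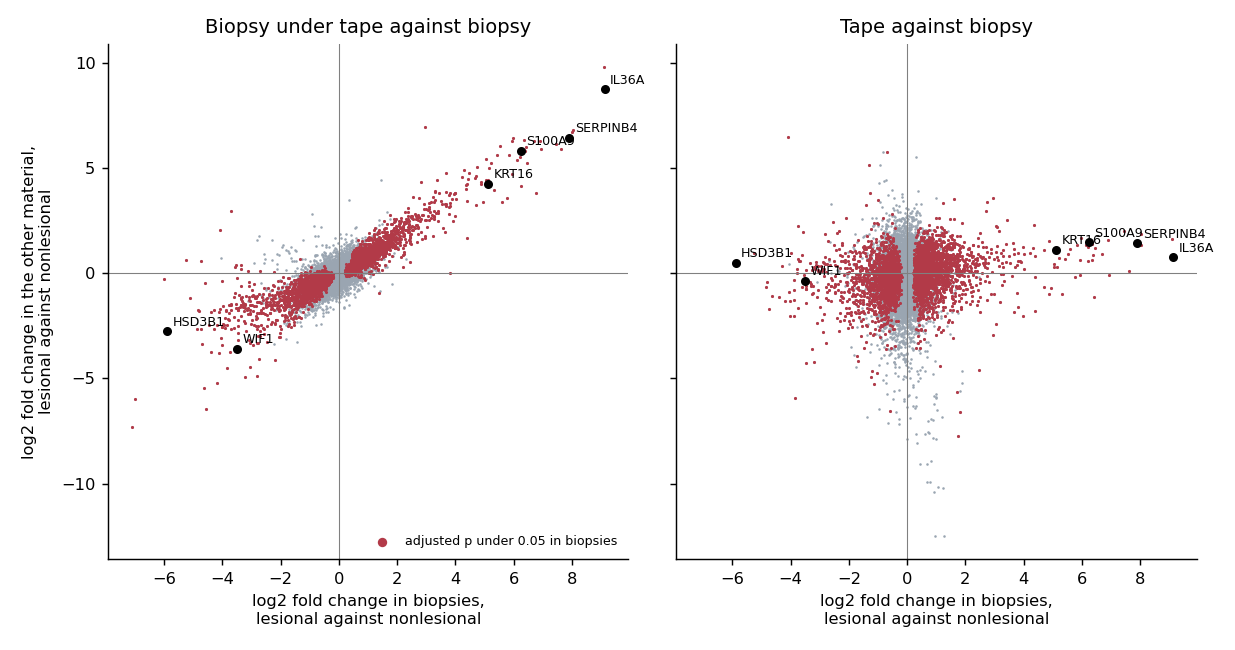
Lesional against nonlesional log2 fold change per gene in biopsies under tape (left) and in tape (right), each against intact biopsy, with S100A9, SERPINB4, KRT16, IL36A, WIF1 and HSD3B1 marked in black. The Pearson correlation across genes was 0.098 in tape and 0.831 in biopsies under tape.

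The change was also compared by patient. For 42 genes in the 9 patients with all 4 samples, each patient's lesional minus nonlesional difference in tape was set against that in biopsy. The median Pearson correlation was 0.08, and 0 genes passed adjustment (2 at unadjusted permutation p under 0.05). The largest Pearson correlation, for the Langerhans cell gene CD207, was 0.80 (exact permutation p = 0.0106, adjusted p = 0.444), and the largest Spearman correlation, for CCL20, was 0.87 (exact permutation p = 0.00451, adjusted p = 0.189).

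Lesional biopsies (n = 10) were next set against healthy ones (n = 5). In the IL-17 response 27 of 29 members rose (28 adjusted over the list alone), at camera adjusted p = 1.06e-17 and adjusted p = 0.286 with an estimated correlation. DEFB4A and IL19 had no counts in healthy biopsies and were at least 864-fold and 399-fold higher. S100A7A (log2 fold change 10.84, SE 1.23, adjusted p = 4.3e-06), SERPINB4 (10.19), PI3 (9.48), S100A9 (8.35) and KRT16 (5.16) rose, with adjusted p-values up to 2.44e-05. Interferon genes (25 of 26 up, 25 adjusted over the list alone, camera adjusted p = 1.31e-18) and proliferation genes (23 of 24 up, 23 adjusted over the list alone, camera adjusted p = 3.62e-14) rose, with adjusted p = 0.286 and 0.287 with an estimated correlation. RRM2 rose by 2.82. Suprabasal keratinocyte genes shifted upward: 8 of 16 members rose (9 adjusted over the list alone), at camera adjusted p = 3.32e-05 and adjusted p = 0.32 with an estimated correlation. The keratin KRT1 rose by 0.95 (adjusted p = 0.0283). Stromal lists fell in part. For fibroblasts and matrix 9 of 20 members fell (9 adjusted over the list alone), at camera adjusted p = 0.000396 and adjusted p = 0.502 with an estimated correlation. The fibulin gene FBLN1 fell by 1.85. For endothelium 9 of 16 members fell (10 adjusted over the list alone), at camera adjusted p = 9.47e-05 and adjusted p = 0.32 with an estimated correlation. The tight-junction gene CLDN5 fell by 1.30. Mitochondrially coded transcripts all fell (13 of 13 down, 13 adjusted over the list alone, camera adjusted p = 3.26e-10), with adjusted p = 0.286 with an estimated correlation. The cytochrome b gene MT-CYB fell by 1.12. HSD3B1 (-4.09), GAL (-3.97), HAO2 (-3.90) and AADACL3 (-3.79) had the largest falls of named genes. A pseudogene whose counts came mostly from 1 donor is not named. The edgeR test called 3172 rises and 2627 falls, 1241 and 1104 of at least 2-fold, and 2624 rises and 3135 falls with upper-quartile scaling.

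Lesional and healthy skin differed in tape too (n = 10 and 5), healthy libraries being the shallowest of the series. IL-17 response genes rose: 23 of 29 members rose (25 adjusted over the list alone), at camera adjusted p = 1.11e-25 and adjusted p = 0.0495 with an estimated correlation. Their median log2 fold change was 5.57. PI3 (log2 fold change 8.04, SE 1.35, adjusted p = 0.000164), S100A8 (7.83), S100A7 (6.53), the cytokine IL36G (7.44), KRT16 (6.24) and KRT6A (5.81) were among them, with adjusted p-values up to 0.000433. Type I interferon genes rose in part (5 of 26 up, 8 adjusted over the list alone, camera adjusted p = 2.34e-11), with adjusted p = 0.0363 with an estimated correlation. IFI27 rose by 4.30 and OASL rose by 3.22. Cornification genes rose too, early (15 of 18 up, 17 adjusted over the list alone, camera adjusted p = 1.65e-18) and late (9 of 25 up, 17 up and 1 down adjusted over the list alone, camera adjusted p = 2.7e-06), with adjusted p = 0.0637 and 0.346 with an estimated correlation. SPRR2B rose by 7.38 and TGM3 rose by 5.35. Suprabasal keratinocyte genes (7 of 15 up, 14 adjusted over the list alone, camera adjusted p = 1.76e-14) included the gap junction gene GJB2 (5.62) and KRT1 (5.13), with adjusted p = 0.0363 with an estimated correlation. Barrier lipid genes (5 of 18 up, 11 adjusted over the list alone, camera adjusted p = 3.22e-11), small structural RNAs (5 of 10 up, 8 adjusted over the list alone, camera adjusted p = 1.36e-11) and immediate early genes (3 of 18 up, 7 adjusted over the list alone, camera adjusted p = 4.92e-09) shifted with them, with adjusted p = 0.0363, 0.0363 and 0.0363 with an estimated correlation. BCL2A1, a survival gene of inflamed tissue, had no counts in healthy tape and was at least 14.6-fold higher, and the linker histone HIST1H1C at least 112-fold. Among the largest falls was the long noncoding RNA LINC00158 (-10.03). Among 20873 genes edgeR called 626 rises and 435 falls. With DESeq2 size factors, which put the median of all genes at -1.336 against -0.199, it called 302 and 1855, while the DESeq2 test called 523 and 2417 and voom 1383 and 6796. The edgeR count was 637, 607 and 601 without healthy replicates 1, 2 and 3.

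Nonlesional skin was next compared with healthy skin. In intact biopsies (n = 9 and 5) edgeR called 0 genes, with 2052 at unadjusted p under 0.05, 113 by DESeq2 and 561 by voom. S100A7 stood at log2 fold change 2.69, SE 0.79, adjusted p = 0.258 and IL36G at 1.92, adjusted p = 0.256. As lists, IL-17 response genes (0 of 29 passing, 7 up adjusted over the list alone, camera adjusted p = 0.000182), small proline-rich and LCE3 genes (0 of 17 passing, 9 up adjusted over the list alone, camera adjusted p = 2.38e-09) and suprabasal keratinocyte genes (0 of 16 passing, 3 up adjusted over the list alone, camera adjusted p = 1.04e-09) lay higher, with adjusted p = 0.66, 0.42 and 0.42 with an estimated correlation. The fibroblast list (camera adjusted p = 1.12e-07) lay lower, with adjusted p = 0.487 with an estimated correlation. In biopsies under tape (n = 10 and 5) S100A7 rose (log2 fold change 4.34, SE 0.65, adjusted p = 0.00916) and 1 pseudogene, not named, fell, with 1663 genes at unadjusted p under 0.05, 33 by DESeq2 and 30 by voom. Upper-quartile factors gave 3 rises and 1 fall, and without healthy replicate 3 the count was 0. The IL-17 list lay higher there too (1 of 29 up, 7 adjusted over the list alone, camera adjusted p = 6.63e-08), with adjusted p = 0.682 with an estimated correlation.

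In tape the nonlesional samples (n = 10) differed from healthy tape (n = 5) in IL-17 response genes: 20 of 29 members rose (23 adjusted over the list alone). The list had a median log2 fold change of 4.60, at camera adjusted p = 7.92e-16 and adjusted p = 0.214 with an estimated correlation. S100A7 (log2 fold change 5.40, SE 1.12, adjusted p = 0.00973), S100A8 (6.49), S100A9 (5.68), PI3 (6.44), KRT16 (5.13), KRT6A (4.88), the iron-sequestering LCN2 (4.47) and CXCL8 (5.66) rose, with adjusted p-values up to 0.028. BCL2A1 and the hydroxy-acid receptor HCAR3 were at least 8.78-fold and 8.97-fold higher. Small proline-rich and LCE3 genes rose (11 of 18 up, 18 adjusted over the list alone, camera adjusted p = 3.12e-13), with adjusted p = 0.214 with an estimated correlation. SPRR2B rose by 6.43. Suprabasal keratinocyte genes (5 of 15 up, 13 adjusted over the list alone, camera adjusted p = 2.4e-13) included GJB2 (4.65) and KRT1 (4.41), with adjusted p = 0.0474 with an estimated correlation. Hair genes (3 of 15 up, 6 adjusted over the list alone, camera adjusted p = 0.0402) included KRT31 (8.13) and KRT86 (6.21), with adjusted p = 0.512 with an estimated correlation. KRTAP1-5 rose by 9.21, among the 5 largest rises. These hair values rested on the 2 nonlesional libraries that held most hair shaft CPM, since the group medians given above were close. Small structural RNAs (4 of 10 up, 8 adjusted over the list alone, camera adjusted p = 2.3e-12) and immediate early genes (2 of 18 up, 11 adjusted over the list alone, camera adjusted p = 1.91e-09) shifted up, with adjusted p = 0.0474 and 0.0474 with an estimated correlation. CCDC166 was at least 125-fold lower, and PAN2, a deadenylase subunit, fell (-5.58). Among 20873 genes edgeR called 250 rises and 19 falls, 25 and 30 with DESeq2 size factors (median of all genes -1.129 against -0.135), and DESeq2 249 and 459. The count rested on single healthy libraries: it was 0 without healthy replicate 1 (2239 at unadjusted p under 0.05), 4 without replicate 2, 52 without replicate 3, 164 without replicate 4 and 64 without replicate 5.

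**Figure D3:**
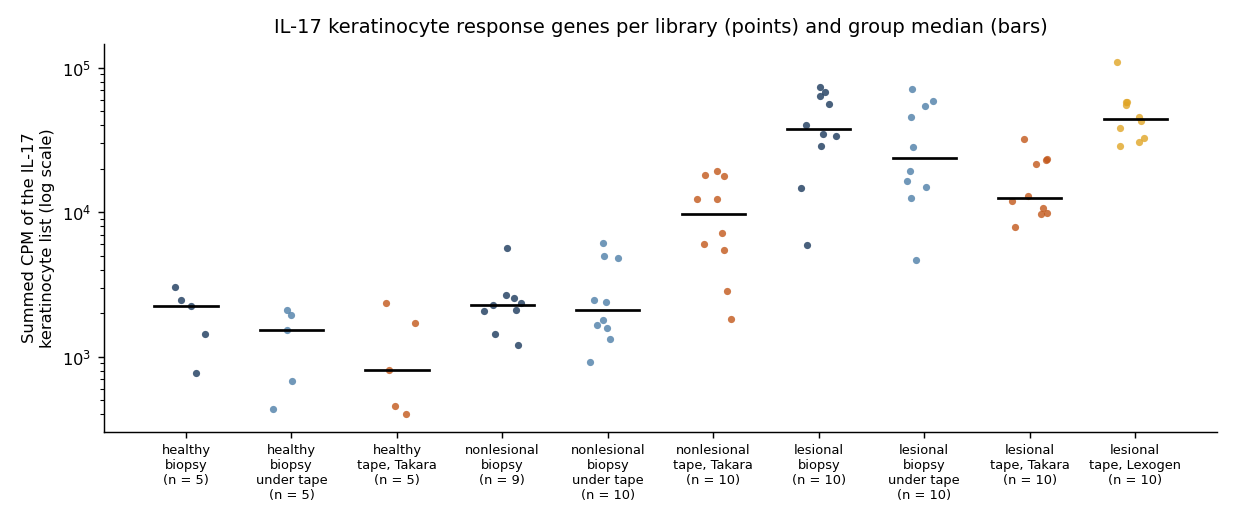
Summed CPM (ribosomal RNA in the total) of the IL-17 list per library (points, log axis) and group median (bars). Medians were 813 in healthy, 9699 in nonlesional and 12501 in lesional Takara tape, and 2253, 2288 and 37455 in the matching intact biopsies.

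Tape was compared with intact biopsy within each kind of skin. The kit of the biopsies was assumed, and a kit other than that of tape would be confounded with sampling here. Small structural RNAs and ribosomal proteins, which led the lists named in lesional skin, also differed between kits. In lesional skin (n = 10 each), small structural RNAs rose throughout: 10 of 10 members rose (10 adjusted over the list alone), at camera adjusted p = 2.52e-23 and adjusted p = 0.00309 with an estimated correlation. RNU11 of the minor spliceosome rose by 18.00 (SE 1.52, adjusted p = 1.42e-10). Ribosomal protein genes fell: 25 of 26 members fell (26 adjusted over the list alone), at camera adjusted p = 5.8e-11 and adjusted p = 0.693 with an estimated correlation. RPS28 fell by 4.93. Late cornification genes, made in the outermost living layer, rose (17 of 25 up, 17 up and 3 down adjusted over the list alone, camera adjusted p = 1.08e-05), with adjusted p = 0.693 with an estimated correlation. LCE1F rose by 5.13 and KPRP rose by 3.90. IL-17 response genes rose in part (15 up and 3 down of 29, 16 up and 5 down adjusted over the list alone, camera adjusted p = 0.000568), with adjusted p = 0.693 with an estimated correlation. IL36A rose by 4.31, CXCL8 by 5.01 and SERPINB3 by 3.30, and the cytokine subunit IL23A rose by 6.99. Basal keratinocyte genes (9 of 16 down, 10 adjusted over the list alone, camera adjusted p = 0.043 and 0.0524 with the replicate block), fibroblast genes (8 of 20 down, 8 adjusted over the list alone, camera adjusted p = 0.000999) and mast cell genes (5 of 10 down, 5 adjusted over the list alone, camera adjusted p = 0.0422) fell, with adjusted p = 0.693, 0.693 and 0.693 with an estimated correlation. KRT15 stood at -2.03, the collagen-binding proteoglycan DCN at -4.06 and the mast cell protease CPA3 at -3.38. KRT1 (-2.54) and KRT10 (-2.81) of the suprabasal layers fell as well.

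In nonlesional skin (n = 10 and 9) IL-17 response genes were higher in tape (23 of 26 up, 23 adjusted over the list alone, camera adjusted p = 1.26e-15), with adjusted p = 0.59 with an estimated correlation. IL36A rose by 12.49 (SE 1.21, adjusted p = 1.36e-09) and SERPINB3 rose by 8.13. Small proline-rich and LCE3 genes (15 of 16 up, 16 adjusted over the list alone, camera adjusted p = 1.44e-08), late cornification genes (17 up and 3 down of 25, 17 up and 3 down adjusted over the list alone, camera adjusted p = 0.000513) and small structural RNAs (10 of 10 up, 10 adjusted over the list alone, camera adjusted p = 3.14e-21) rose, with adjusted p = 0.598, 0.62 and 0.0147 with an estimated correlation. Falls covered fibroblasts (18 of 20 down, 20 adjusted over the list alone, camera adjusted p = 1.55e-07), smooth muscle (1 up and 12 down of 14, 1 up and 12 down adjusted over the list alone, camera adjusted p = 0.00273), sebaceous genes (17 of 22 down, 18 adjusted over the list alone, camera adjusted p = 0.0262), sweat glands (11 of 14 down, 11 adjusted over the list alone, camera adjusted p = 0.0234) and ribosomal proteins (26 of 26 down, 26 adjusted over the list alone, camera adjusted p = 3.37e-13), with adjusted p = 0.598, 0.598, 0.707, 0.683 and 0.598 with an estimated correlation. The sweat gland secretory genes PIP (-8.26), SCGB1D2 (-7.67) and DCD (-7.50) had 3 of the 5 largest falls. LUM of the dermal matrix (-5.29) and KRT2 (-4.35) fell. In healthy skin (n = 5 each) keratinocyte genes were lower in tape. Suprabasal (16 of 16 down, 16 adjusted over the list alone, camera adjusted p = 0.000206), basal (13 of 16 down, 13 adjusted over the list alone, camera adjusted p = 0.000996) and fibroblast genes (19 of 20 down, 19 adjusted over the list alone, camera adjusted p = 2.71e-07) fell, with adjusted p = 0.499, 0.499 and 0.203 with an estimated correlation. KRT1 fell by 6.85 (SE 0.78, adjusted p = 9.81e-07), and KRT10 stood at -5.55 and DCN at -8.82. Of B and plasma cell genes 5 of 7 rose (5 adjusted over the list alone). Camera adjusted p was 0.00736, and 0.203 with an estimated correlation. Healthy tape held a median of 6.65% of counts in genes chosen for lying under 0.1 CPM in every biopsy group. The B cell gene PAX5 rose by 8.94 and the testis-expressed gene TEX101 rose by 14.31. The edgeR test called 2403 rises and 3302 falls in lesional, 2996 and 3714 in nonlesional and 5376 and 6313 in healthy skin. The balance depended on the scaling. The median gene lay at -0.493, -0.301 and -0.351 with TMM and at 0.234, 0.295 and 0.458 with upper-quartile factors. The latter called 4129 and 1893, 4380 and 2177, and 6935 and 3978. With the replicate block, lesional calls were 1033 and 5443 and nonlesional calls 1292 and 4646.

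Between biopsies under tape and intact biopsies edgeR called 0 genes in lesional (1229 at unadjusted p under 0.05; DESeq2 1), nonlesional (286; DESeq2 0) and healthy skin (173; DESeq2 1), and voom called 0 in each. As lists, late cornification genes (camera adjusted p = 6.2e-11) and suprabasal keratinocyte genes (camera adjusted p = 2.3e-08) lay lower under tape in lesional skin, and fibroblast genes (camera adjusted p = 2.41e-09) higher, with medians of -0.95, -0.58 and 0.60, with adjusted p = 0.62, 0.62 and 0.62 with an estimated correlation. In nonlesional skin T cell genes (median -0.41, camera adjusted p = 2.99e-10) and neutrophil genes (median -0.49, camera adjusted p = 4.11e-07) lay lower, and adipocyte genes (median 1.01, camera adjusted p = 1.1e-09) higher, with adjusted p = 0.277, 0.0106 and 0.277 with an estimated correlation. In healthy skin hair follicle genes lay higher (median 3.77; 0 of 13 members passed (10 adjusted over the list alone), camera adjusted p = 1.24e-05) and sebaceous genes lower (median -1.32, camera adjusted p = 9.34e-13), with adjusted p = 0.891 and 0.798 with an estimated correlation.

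The 2 library kits were compared on the same 10 lesional tape samples. Lexogen libraries held more of the ribosomal protein genes (18 of 26 up, 21 adjusted over the list alone, camera adjusted p = 1.46e-12), with adjusted p = 0.669 with an estimated correlation. RPS29 rose by 8.56 (SE 0.78, adjusted p = 1.56e-10) and RPLP1 rose by 5.16. Mitochondrially coded genes rose with them (7 of 13 up, 9 adjusted over the list alone, camera adjusted p = 9.28e-06), with adjusted p = 0.688 with an estimated correlation. MT-ND3 rose by 6.29 and MT-CO3 rose by 6.12. Small structural RNAs, which lack a poly(A) tail, fell (9 of 10 down, 10 adjusted over the list alone, camera adjusted p = 3.36e-15), with adjusted p = 0.0073 with an estimated correlation. RPPH1 fell by 10.99, RMRP fell by 8.54 and RNA5SP149, a 5S ribosomal RNA pseudogene, fell by 16.18. Members of the IL-17 list went both ways (3 up and 3 down of 28, 3 up and 4 down adjusted over the list alone, camera adjusted p = 0.172 and 0.0333 with the replicate block). C15orf48 (4.50) and SERPINB4 (2.34) rose, and LCN2 (-2.46), KRT17 (-1.80) and IL36A (-3.18) fell. The small proline-rich and LCE3 list did the same (5 up and 3 down of 17, 6 up and 4 down adjusted over the list alone, camera adjusted p = 0.0408), with adjusted p = 0.714 with an estimated correlation. SPRR2E rose by 3.49, and SPRR1A (-4.50) and IVL (-2.59) fell, as did LCE1D (-7.52) and TGM3 (-2.50) of late cornification. Of 7363 genes edgeR called 512 rises and 517 falls, and with the replicate block 737 and 815. The DESeq2 test called 753 and 3430, and edgeR without a low-count filter 1993 and 6882. Across the 10 patients, levels of 13 of 42 genes correlated between kits after adjustment, with a median Pearson correlation of 0.56, and 6 by Spearman correlation. Among the highest values were 0.98 for LCN2, 0.97 for CXCL8, 0.94 for KRT10 and 0.92 for SERPINB4. Without the libraries that stood apart in make-up, 2 of the 42 passed, and 0 by Spearman.

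**Figure D4:**
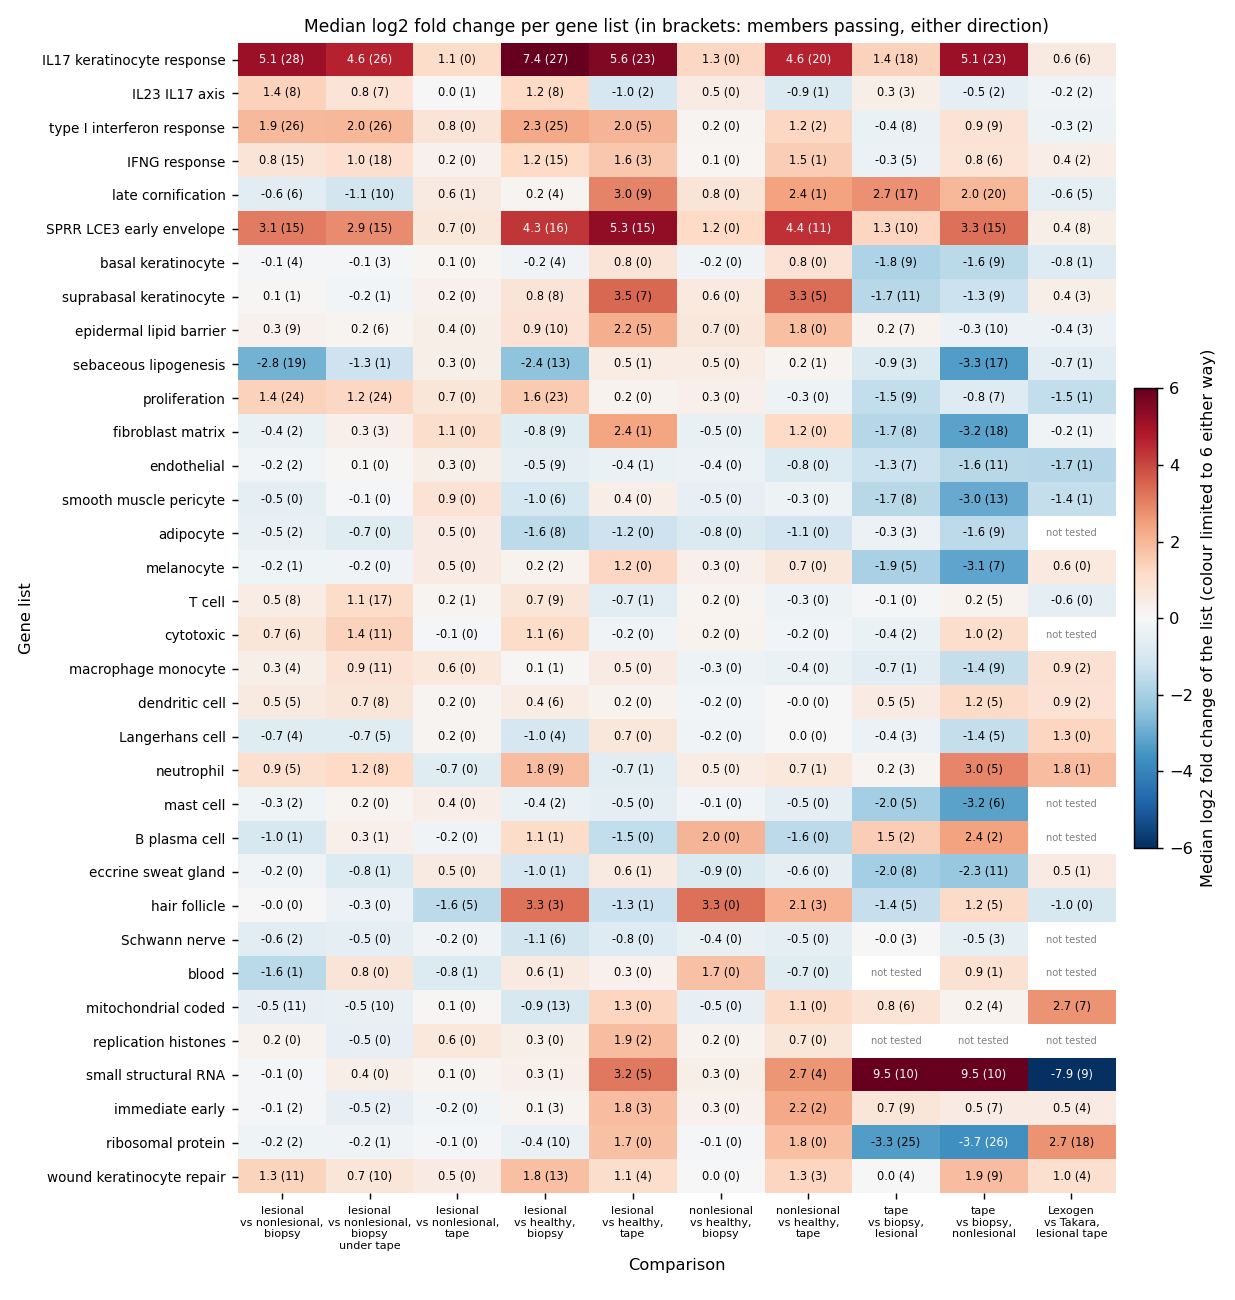
Median log2 fold change of each of the 34 gene lists (colour) in 10 comparisons, with the number of members passing in each cell. The IL-17 response list had medians of 5.13 in lesional against nonlesional biopsies, 1.12 in the same contrast in tape and 4.60 in nonlesional against healthy tape.

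Over all 17 comparisons camera called 257 of 564 list tests with its preset correlation, and 21 of these held with an estimated correlation. The 21 were type I interferon and wound-repair genes in lesional against nonlesional tape, and in biopsies under tape the IL-17, type I interferon, interferon-gamma, small proline-rich, cytotoxic and neutrophil lists. In lesional against healthy tape they were the IL-17, interferon, suprabasal, barrier lipid, small RNA and immediate early lists, and in nonlesional against healthy tape the suprabasal, small RNA and immediate early lists. The small RNA list held in lesional and nonlesional tape against biopsy and in Lexogen against Takara, and the neutrophil list in nonlesional biopsies under tape against intact biopsies.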

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

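The tests of carried-over RNA and of scaling were chosen after the results they bear on had been seen. The splits of the libraries and the interaction were not. The test of depth used a setting added after the data were seen, with its bounds set before its result.

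The lesional effect on keratinocyte genes was smaller in tape than in biopsies by the main test of the difference, which did not hold under every setting. Of 19333 genes, 159 had a lesional effect that differed between tape and intact biopsy by edgeR. Among them were IL36A (difference in log2 fold change -8.20, adjusted p = 0.00125), SERPINB4 (-6.52, adjusted p = 0.00128), S100A8 (-4.46, adjusted p = 0.00867), KRT16 (-4.00, adjusted p = 0.00344) and HSD3B1 (6.26, adjusted p = 0.0351). The effect in biopsies was 9.13 for IL36A and 5.84 for S100A8, and in tape 0.75 and 1.34. With the replicate block 37 genes were called, and with a weight per material 0, none of 12 named genes among them. The IL-17 list had adjusted p = 0.467 with an estimated correlation, and 10 of 50 random splits reached the count of 159.

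In nonlesional tape the IL-17 response genes stood high. Their summed CPM was 9699 in nonlesional, 12501 in lesional and 813 in healthy tape, against 2288 in nonlesional biopsies, and 20 of 29 members rose against healthy tape (camera adjusted p = 7.92e-16; adjusted p = 0.214 with an estimated correlation). Low depth of healthy tape did not account for it, since at 200000 counts per library the median log2 fold change was 4.25 and 18 of 22 members passed. A scaling error would move lists alike, but the IL-17 median exceeded that of late cornification genes (2.42) by 2.18. With DESeq2 size factors the IL-17 median was 3.34 and 8 of 29 members passed, so scaling moved the count. Lesional RNA spread evenly over all tape was argued against as the whole cause, since healthy tape would then stand as high (exact permutation p = 0.000666). As a part it cannot be told apart, because healthy tape held a 0.0838 share of the nonlesional level and no tape free of it was sampled. The calls depended on single healthy libraries. Without replicate 1 the list median was 4.67 (median SE 1.27) against 4.60 (1.20), but the smallest adjusted p rose from 0.00711 to 0.0582 and 0 of 30 members passed, and without replicate 2 only 1 did. Carry-over within a patient, a state of uninvolved skin and a general difference in keratinocyte RNA between the tapes remain open and untested.

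Some libraries lay far from the rest of their group, the gap to the nearest other being large against the group's range in 11 of 50 checks, where chance marks about 1 in 20 groups. Total counts were lowest in 1 healthy biopsy (10699308), 1 nonlesional biopsy (9945190) and 1 nonlesional biopsy under tape (10549547), and highest in 1 nonlesional tape library (11692646). Genes with at least 5 counts were lowest in 1 healthy biopsy (18035) and 1 lesional biopsy (17730). Ribosomal RNA features took the lowest share in 1 healthy biopsy under tape (0.204%) and 1 nonlesional tape library (7.15%), and the highest in 1 nonlesional (0.685%) and 1 lesional biopsy under tape (1.05%). Nuclear protein-coding genes took 80.7% in 1 nonlesional tape library.

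Calls were also counted in 50 or 100 random splits per comparison into groups of the same sizes, the real one included. Chance was argued against where only the real split reached its count, at 1 in 50 or 100 and uncorrected over comparisons. This held for lesional against nonlesional biopsies (4469 genes, highest other split 1331), the same beneath tape (2930 and 500), lesional against healthy biopsies (5799 and 3618) and tape (1061 and 707), and nonlesional against healthy tape (269 and 42). It held too for tape against biopsy in lesional (5705 and 470), nonlesional (6710 and 753) and healthy skin (11689 and 0) and for the kits (1029 and 0). Chance was left open for lesional against nonlesional tape (181), where 3 of 50 splits reached the count and another called 493. For the lesional effect of tape minus biopsy (159), 10 of 50 splits reached it and another called 501, which points to a structure of the libraries. With the replicate block these counts were 17 and 37. Chance was left open too for nonlesional against healthy biopsies beneath tape (2, reached by 5 of 100, highest 43). A count of 0 is reached by any split, so the splits decide nothing there. This was so for nonlesional against healthy biopsies (all 100 splits, highest 6), biopsies under tape against intact biopsies (all 50, highest 0 in lesional and 1 each in nonlesional and healthy skin) and the matching difference in lesional effect (all 50, highest 2). Genes at unadjusted p under 0.05 and DESeq2 calls beside these counts of 0 are given above.

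Splits that part the 2 libraries of each donor hold donor differences apart from the groups. Among 50 of these only the real split reached its count for lesional against nonlesional biopsies (highest other 389), tape (77) and biopsies under tape (422), tape against lesional (451) and nonlesional biopsies (1532), the kits (312) and the lesional effect of tape minus biopsy (66). Counts of 0 again decide nothing. For biopsies under tape against intact biopsies all 50 reached 0, and none called more, in lesional and nonlesional skin. For the matching difference in lesional effect all 50 reached 0 and another called 3645, which points to a structure of the libraries. In healthy skin 16 such splits are too few for a share under 0.05, with 11689 genes in the real split and 0 in the highest other for tape, and 0 in all 16 for biopsies under tape.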

How the results depend on the processing

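Settings chosen after the data were seen were ribosomal RNA features left out, libraries that stood apart in make-up left out, thinning to 200000 counts, and the combinations of the second with the block and of shallow libraries with only 2 groups. Genes named in the text kept direction under each setting. Of named genes past the threshold, 179 of 184 stayed past it with the DESeq2 test, 178 of 188 with DESeq2 size factors, 185 of 188 with upper-quartile factors, 186 of 188 without a low-count filter, 156 of 188 with voom, 0 of 12 with a weight per material, 134 of 135 at 1 depth, 96 of 96 without the libraries that stood apart and 30 of 36 without shallow libraries. Without healthy replicates 1 to 5 the numbers lost were 23, 19, 13, 7 and 7. Thinned to the smallest intact biopsy library, of 9945190 counts as deposited, 4106 genes were called between lesional and nonlesional biopsies (4469 at full depth). Beneath tape, where the smallest library held 10117090 counts, 2627 were called (2930 at full depth). Both depths lay above the tape medians, so these counts do not show what tape depth would leave. In tape, where counts outside ribosomal RNA features had medians of 899284 in lesional and 340255 in nonlesional skin, the limit set by depth was not isolated. Shallow libraries could not be left out, nor libraries thinned to 1 depth, where healthy tape was compared, since all 5 held under 1000000 counts. Fewer libraries or genes entered each smaller fit, and for the other values below the cause was not tested.

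Counts of called genes moved by over 1.5 times as follows. A 2-fold minimum left 1494 of the genes called between lesional and nonlesional biopsies, 1080 beneath tape and 2345 between lesional and healthy biopsies. DESeq2 called 2940 for lesional and 708 for nonlesional against healthy tape, 113 and 33 for nonlesional against healthy biopsies intact and beneath tape, 15004, 17366 and 19936 for tape against biopsy in lesional, nonlesional and healthy skin, 1 each in lesional and healthy skin for biopsies under tape against intact, and 4183 between kits. With DESeq2 size factors the counts were 2157 and 55 for lesional and nonlesional against healthy tape, and with upper-quartile factors 4 for nonlesional against healthy biopsies beneath tape. Voom called 8179 and 2888 against healthy tape, 561 and 30 for nonlesional against healthy biopsies intact and beneath tape, 8872 for lesional tape against biopsy, 2132 between kits and 52 for the lesional effect of tape minus biopsy. With a weight per material that last count was 0, with 756 at unadjusted p under 0.05. Without a low-count filter edgeR called 586 between lesional and nonlesional tape, 1801 and 523 against healthy tape, 1 and 6 for nonlesional against healthy biopsies intact and beneath tape, 17681, 17603 and 20222 for tape against biopsy, 8875 between kits and 309 for the interaction with tape.

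Depth and libraries moved counts too. Lesional against nonlesional tape had 3 calls without shallow libraries (3 again with only the 2 groups fitted), 0 at 1 depth, with 5 nonlesional libraries (69 at unadjusted p under 0.05), 27 with only the 2 groups, and 316 without the libraries that stood apart. At 1 depth the counts were 80 for the interaction with tape, 2 and 4 for nonlesional against healthy biopsies intact and beneath tape, and 3734 and 3277 for tape against lesional and nonlesional biopsies. At 200000 counts healthy tape against biopsy had 2036. Without the libraries that stood apart the counts were 902 for the interaction, 723 for nonlesional against healthy tape, 9488 for lesional tape against biopsy, and 2 of 42 genes correlated between kits. Leaving out each healthy replicate in turn gave 601 to 806 calls for lesional and 0 to 164 for nonlesional against healthy tape (0 without replicate 1), 4710 to 5081 for lesional and 0 to 1 for nonlesional against healthy biopsies, 0 to 2 beneath tape (0 without replicate 3), and 10684 to 12515 for healthy tape against biopsy. Genes detected in tape over biopsy had a ratio of 0.657 in lesional and 0.744 in nonlesional skin at 1 depth (adjusted permutation p = 0.0599 each), so these no longer passed, but at a minimum of 10 counts both did (ratios 0.518 and 0.595, adjusted permutation p = 0.0101 each; adjusted sign-flip permutation p = 0.125 and 0.25 within donors), as at 200000 counts (0.363 and 0.456, adjusted permutation p = 0.0004 and 0.000217). In healthy skin the ratio was 0.48 at a minimum of 10 counts (adjusted exact permutation p = 0.0265) and, at 200000 counts, 0.866 at that minimum (adjusted exact permutation p = 0.0397) and 1.12 at a minimum of 5 (adjusted exact permutation p = 0.179).

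The replicate block gave 17 calls between lesional and nonlesional tape, 72 without the libraries that stood apart and 0 without shallow ones (68 at unadjusted p under 0.05), 1552 between kits, and 37 for the interaction with tape, 293 without the libraries that stood apart. The share of genes with the same direction as in intact biopsy was 55.6% for tape and 81.2% for biopsies under tape with the block, and 50.6% for tape without the libraries that stood apart. The Pearson correlation for tape was 0.222 with the block, 0.166 over genes with at least 10 CPM and 0.039 (Spearman 0.021) without the libraries that stood apart. With the block the direction given by camera turned from up to down, none being called, for B and plasma cells (main median -0.97, adjusted p with the block = 0.877), replication histones (main median 0.20, 0.46) and small structural RNAs (main median -0.11, 0.916) in lesional against nonlesional biopsies. Beyond the changes given beside the results, the block changed no other call of a gene or list in the comparison for which it is named. Over all lists it added 27 calls and ended 16, and in lesional against nonlesional tape 9 lists were called with it and 16 without. Of 564 list tests camera called 257, 21 with an estimated correlation, and fry 132, 95 of them shared. With the block 184 of 393 were called, where 173 were called without it, 157 in both. In lesional tape against biopsy the sign of fry opposed that of camera, none called by fry, for dendritic cells (median 0.50, fry adjusted p = 0.479), barrier lipids (0.20, 0.068) and neutrophils (0.16, 0.545).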

Other observations

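The tests of leading features, of library depth, of hairs and of follicle loss were chosen after the results they bear on had been seen, and the test of gene length before. Structural tissues of the dermis lay lower in lesional than in healthy biopsies. Smooth muscle and pericyte genes fell in part (6 of 14 down, 11 adjusted over the list alone, camera adjusted p = 0.000487), with adjusted p = 0.405 with an estimated correlation. The muscle filament gene DES fell by 1.87 and the actin-binding TAGLN fell by 1.09. Of adipocyte genes (8 of 13 down, 10 adjusted over the list alone, camera adjusted p = 4.51e-05), the hormone-sensitive lipase LIPE fell by 1.74 and the fatty acid carrier FABP4 fell by 1.06, with adjusted p = 0.32 with an estimated correlation. Of Schwann cell genes (6 of 9 down, 6 adjusted over the list alone, camera adjusted p = 0.00035), the adhesion gene NCAM1 fell by 1.37, with adjusted p = 0.32 with an estimated correlation. Neutrophil genes rose (9 of 13 up, 10 adjusted over the list alone, camera adjusted p = 9.47e-05), with adjusted p = 0.286 with an estimated correlation. The formyl peptide receptor FPR1 rose by 3.33. Of T cell genes (9 of 21 up, 13 adjusted over the list alone, camera adjusted p = 9.47e-05), the costimulatory receptor ICOS rose by 2.24, with adjusted p = 0.413 with an estimated correlation.

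Single immune and pigment genes also differed between lesional tape and biopsies, in lists that did not pass as sets. Dendritic cell genes went both ways (4 up and 1 down of 16, 4 up and 1 down adjusted over the list alone, camera adjusted p = 0.113), since the integrin ITGAX rose by 3.53 and the costimulatory ligand CD80 rose by 3.72, while the lymphoid chemokine CCL19 fell by 3.24. Of neutrophil genes (3 of 11 up, 3 adjusted over the list alone, camera adjusted p = 0.19), the G-CSF receptor CSF3R rose by 3.61. Of melanocyte genes (5 of 10 down, 2 up and 6 down adjusted over the list alone, camera adjusted p = 0.161), PMEL of the melanosome stood at -2.62. Barrier lipid genes split (3 up and 4 down of 18, 3 up and 4 down adjusted over the list alone, camera adjusted p = 0.468). The lipoxygenase ALOX12B rose by 2.16 and the lipase cofactor ABHD5 rose by 2.58, while the ceramide synthase CERS3 fell by 1.67 and the elongase ELOVL1 fell by 2.17.

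Genes under 0.1 CPM in every biopsy group (5811) were summed. Their median share of counts was 6.65% in healthy, 2.13% in nonlesional and 1.82% in lesional Takara tape and 0.544% in Lexogen tape. That choice set their share of about 0.01% in biopsies. Ribosomal RNA is part of these totals, most in lesional tape, so their order is not free of it. Of these genes' healthy tape counts the 10 leading features held 16.2%, so a few loci were not the source. Low RNA input may contribute, though ribosomal RNA was not held fixed: the share fell with depth over the 20 patient Takara tape libraries (Spearman rho -0.68, permutation p = 0.0012; Pearson r -0.73, permutation p = 0.00038; rho -0.62 without the 2 farthest, -0.77 within lesional and -0.82 within nonlesional tape). Reads spread over the genome by gene length cannot be told apart. The counts followed length with rho 0.554 over the 2990 genes with a known length, but these were 51.5% of the set, and with rho 0.384 over 1011 protein-coding ones. No biological explanation was tested.

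Hair shaft genes were uneven among nonlesional tape libraries, 2 of which held 95.7% of the summed CPM, as hairs caught on few tapes would give. The other 8 libraries also exceeded lesional tape (medians 418 and 52.9 CPM; exact permutation p = 0.00752). Ribosomal RNA, with a larger share in lesional tape, is part of these totals, so whether hairs were the whole cause stays open. Loss of follicles from lesional skin was argued against, since the hair follicle list had a median of -0.02 between lesional and nonlesional biopsies.

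Single features had high medians in healthy tape, with ranges that overlapped those of nonlesional tape. TEX101, a testis-expressed gene, had a median of 2504 counts per library in healthy (1305 to 5249), 375 in nonlesional (20 to 5357) and 73 in lesional tape, and 5 in healthy biopsies. The noncoding RNA LINC00158 had medians of 2982 (1 to 3975), 16 (0 to 3010) and 0 in the same tapes and 1 in healthy biopsies. At 200000 counts per library healthy tape gave 8224 genes with at least 5 counts and nonlesional tape 3400 (exact permutation p = 0.000666, adjusted p = 0.00222).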
